A study of Gossypium hirsutum with 5 samples.

How the data were processed

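Transcript abundance was measured by digital gene expression tag sequencing in cotyledons of upland cotton (Gossypium hirsutum, ecotype CCRI10) collected 20 days after germination and 3 h after irrigation. Per the labels' protocols, cDNA bound to beads through its poly(A) end was cut with NlaIII, which recognises CATG, an adaptor carrying an MmeI site was ligated, and MmeI cut downstream, so that each tag holds CATG and the next 17 bases of a transcript. A further adaptor was then ligated at the MmeI end, and the tags were amplified and sequenced. The base caller, read filters and tag-to-gene matching were not given in the sources used here.

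Each deposited file lists, per the file headers, a 21-base tag, its copy number and a TPM value. The copy number is a count of reads of that tag as deposited by the authors, with no scaling. The lowest count in each deposited file is 2, so a tag missing from a file had 0 or 1 copy, and it was entered as 0. The deposited TPM values are counts scaled to the file's own total, and are the same quantity as CPM. Recomputing them from the counts gave a largest difference of 0.00500 TPM in each library, which is the rounding to 2 decimals. No other value was used.

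The groups came from the sample titles and labels: mock irrigation with double distilled water, sodium nitroprusside (SNP, a nitric oxide donor) at 100 µM and at 250 µM, and the nitric oxide scavenger cPTIO at 10 µM. Each treatment was represented by 1 RNA pool. The design text describes the pair of 250 µM SNP libraries as a technical replicate. The only residual degree of freedom (1) is therefore technical, and every test below compares libraries, not conditions.

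No transcript or genome sequence was used. The gene table supplied with the data (Gossypium_hirsutum_v2.1) holds names and positions without sequence, so tags could not be matched to genes. Tags are reported by sequence and count. The gene lists fixed before the data were examined, their medians, the product-name part of the naming rule, and the alternatives that share tags among genes or keep the 3'-most site were not run.

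The 5 libraries held 520056 distinct tags, and 141880 tags with at least 25 copies summed over the libraries were tested. These held 96.3% to 97.1% of the copies of each library. Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, all 5 libraries, 4 groups, TMM scaling of the full library totals). A tag was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Errors on log2 fold changes (SE) are approximate: the absolute fold change divided by the square root of the F statistic of the same test. For values with the offset, the likelihood ratio statistic took the place of F. Each comparison names tags from the 8 highest and the 8 lowest log2 fold changes among called tags with a mean of at least 50 copies over the libraries compared. For 250 µM SNP the log2 ratio also had to be at least 1 in the same direction in each library. The 5 most abundant tags of the mock library are named as well. Any other tag named was chosen after its values were seen. A tag missing from a library was given an upper limit of 4.74 copies per library, the 95% Poisson limit for at most 1 copy, and folds against it are lower bounds. Such limits, and Wilson intervals, cover counting error only, since PCR copies are not independent molecules.

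The alternatives fixed at the outset were scaling by totals alone or by RLE size factors, DESeq2 1.42.0, Fisher's exact test on the summed copies (with 0.5 added for the ratio), no count filter, a minimum of 100 copies, other thresholds, and Fisher's exact test without each 250 µM SNP library. After the data had been seen, 4 more were added: an offset for the last 2 bases of the tag, the likelihood ratio test of edgeR (glmLRT), both together, and the removal of tags that resemble the adaptors. The offset is the median log2 deviation of tags above 10 CPM that share their last 2 bases, per library. Adaptor sequences were those of the Illumina tag-profiling kit, known from general knowledge and not from the labels.

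The calling was tested on simulated data for 250 µM SNP against mock, with 200 changed tags of at least 250 summed copies and no bias. Over 134941 tags, 2.0% of 2-fold changes, which lie at the calling threshold, were recovered with 0 unchanged tags called. Over 134914 tags, 93.5% of 4-fold changes were recovered with 15 unchanged tags called. Among tags of 25 to 99 summed copies (134830 tags tested), 9.5% of 4-fold changes were recovered with 4 unchanged tags called. With the observed effect of the last 2 bases built in (135257 tags, 4-fold changes), the main test recovered 81.5% and called 489 unchanged tags, and the offset with the likelihood ratio test recovered 97.0% and called 35. Every simulated tag was drawn at the dispersion trend fitted without the offset, so no tag had a spread of its own. In the real libraries with the offset, tags did differ in spread (prior degrees of freedom of edgeR 8.02). The simulated false calls therefore do not measure the error of the likelihood ratio test on the real counts. The shared mock library was simulated in 20 draws of unchanged groups without bias, and in 10 draws with the observed effect of the last 2 bases built in, tested by the main test and by the offset with the likelihood ratio test. Further computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.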

Results

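Tag libraries were sequenced from cotton cotyledons 3 h after irrigation with water (mock), with the nitric oxide donor sodium nitroprusside (SNP) at 100 µM or 250 µM, or with the nitric oxide scavenger cPTIO at 10 µM. Mock, 100 µM SNP and cPTIO had 1 library each, and 250 µM SNP had 2 libraries that the design describes as a technical replicate. The listed copies came to 16337052 in mock, 13978274 in 100 µM SNP, 13111729 and 14081025 in 250 µM SNP replicates 1 and 2, and 15751709 in cPTIO. Between 278363 and 320520 distinct tags were listed per library. With 1 plant pool per treatment, no difference between treatments has a replicate check, and the p-values of the main test rest only on the spread of the technical pair. That test pooled the spread over tags (infinite prior degrees of freedom). Its p-values therefore do not reflect how well each single tag repeated within the pair.

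The most abundant mock tag, CATGAGGTGAATTTTTATGTG, ranked first in all 5 libraries. It made up 2.48% of the mock copies (95% Wilson interval 2.47% to 2.49%), 2.60% in 100 µM SNP (2.59% to 2.61%), 1.88% and 1.70% in 250 µM SNP replicates 1 and 2 (1.87% to 1.89% and 1.69% to 1.70%), and 1.48% in cPTIO (1.48% to 1.49%). The next tag, CATGTAATCCTAAAATGTGAC, took 1.67% of mock (1.66% to 1.67%), 1.33% of 100 µM SNP (1.32% to 1.33%), 1.05% and 1.12% of the 250 µM SNP libraries (1.04% to 1.05% and 1.11% to 1.12%), and 0.983% of cPTIO (0.979% to 0.988%). CATGCTCAAAGCATTTTGGCC, the third mock tag, kept that rank in each library and held 0.854% of mock (0.849% to 0.858%) against 0.577% of 100 µM SNP (0.573% to 0.581%). CATGGGCTTATGCCACTAACT had 0.514% of mock (0.510% to 0.517%) and 0.508% of cPTIO (0.505% to 0.512%), but 0.269% of 100 µM SNP (0.267% to 0.272%), where it ranked 18. CATGTTCTTTACTTTTGTTTT had 0.497% of mock (0.494% to 0.501%) and 0.342% of 100 µM SNP (0.339% to 0.345%). None of these 5 tags reached an absolute log2 fold change of 1 in any comparison with the main test. With an offset for the last 2 bases of the tag and the likelihood ratio test, CATGAGGTGAATTTTTATGTG was called lower in cPTIO against mock (log2 fold change -1.24, adjusted p = 0.00032).

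The technical pair asked how well the method repeats. Across 141880 tags, which are not independent replicates, log2(CPM + 1), where CPM is copies scaled by the library total, of the pair had a Pearson correlation of 0.971, equal at this rounding to that of 250 µM SNP replicate 2 with cPTIO (0.971) and above that of 250 µM SNP replicate 1 with cPTIO (0.956). By Fisher's exact test on the reads, 798 tags were higher and 1808 lower in replicate 2 than in replicate 1. The pair differed by more than sampling noise, with a chi-square of 6.30 per degree of freedom over 53704 tags of at least 50 copies, so the libraries were kept separate. The last 2 bases of the tag accounted for 38.6% of the variance of the log2 ratio within the pair, over 14876 tags above 10 CPM. Tags ending in AA had a median log2 ratio of -0.45 in replicate 2 against replicate 1.

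The same bases separated tags in every comparison with mock. They accounted for 59.7% of the variance of log2 ratios in 100 µM SNP, 59.7% and 44.7% in 250 µM SNP replicates 1 and 2, and 25.9% in cPTIO. In 100 µM SNP, tags ending in AA had a median log2 ratio of 1.23 and tags ending in TT of -0.47. Tags ending in GG had medians of 0.96 and 1.18 in 250 µM SNP replicates 1 and 2, against 0.05 in 100 µM SNP and 0.30 in cPTIO. Counts of called tags are therefore given with and without an offset for these bases.

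**Figure D1:**
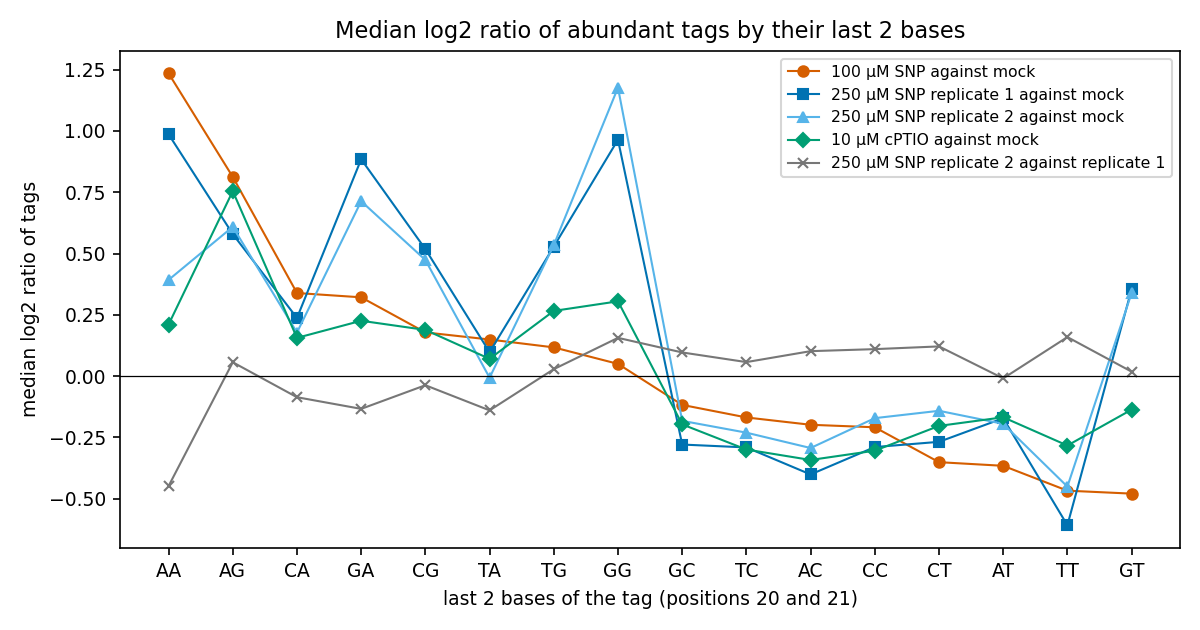
Median log2 ratio (y axis) of tags above 10 CPM, by the last 2 bases of the tag (x axis, ordered by 100 µM SNP), for each library against mock and for the technical pair. Tags ending in AA stand at 1.23 in 100 µM SNP and at -0.45 within the technical pair.

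The comparison of 100 µM SNP with mock asked which transcripts respond to the lower donor concentration. CATGCAAACACACATCTACAG rose from 7 copies in mock to 130 in 100 µM SNP (log2 fold change 4.46 ± 0.53 SE, adjusted p = 3.6e-13) and had 13, 29 and 26 copies in 250 µM SNP replicates 1 and 2 and cPTIO. The related tags CATGTTCCCCCTCCCCTCCCC and CATGTTCCCCCTCCCGTCCCC rose together, by log2 fold changes of 3.42 ± 0.32 (adjusted p = 2.9e-21) and 2.88 ± 0.35 (adjusted p = 1.1e-12), from 55 to 488 and from 42 to 257 copies. The latter differs from the former by C16G, counted from the first base of CATG. The former had 412, 324 and 470 copies in 250 µM SNP replicates 1 and 2 and cPTIO, and the latter 144, 154 and 254. Both were thus lower in mock than in every other library, with the scavenger as with the donor. CATGTTCTTTACTTCTGCTTG fell from 182 to 25 copies (-2.59 ± 0.41, adjusted p = 1.4e-07) and CATGACGGCAAAGAAAGGAAG from 335 to 67 (-2.05 ± 0.33, adjusted p = 1.3e-07). Of the 8 named lower tags, 4 shared at least 6 bases in a row with adaptor 2 of the library kit, CATGACGGCAAAGAAAGGAAG among them. Of these 4, 2 lost their call with the offset and the likelihood ratio test: CATGCCGACGGCATTGGAGCG (-2.70 ± 0.41 in the main test, -2.88 ± 1.12 and adjusted p = 0.175 with the offset) and CATGGAGATTTTGGTGACGGC (-2.05 ± 0.38, then -2.01 ± 0.62 and adjusted p = 0.0542). CATGGCTCCAAGGACAATTCC had 177 copies in mock and was listed in no other library, at least 31.9-fold lower in 100 µM SNP. It differs by C17A from CATGGCTCCAAGGACACTTCC, which had 28346 copies over the 5 libraries. The other 5 named higher tags ended in runs of A and had log2 fold changes of 2.79 to 2.91, which the offset lowered to between 1.55 and 1.68 (adjusted p = 0.0151 to 0.0482). CATGCAAACACACATCTACAG fell to 3.61 ± 0.54 with it (adjusted p = 2.0e-07), while the related pair stood at 3.56 and 3.02, CATGTTCTTTACTTCTGCTTG at -2.70 and CATGACGGCAAAGAAAGGAAG at -2.91. The offset takes 1 median for all tags ending in AA. Among abundant AA tags, those ending in at least 6 A had a median log2 ratio of 1.79 against mock, and the others 1.06. The folds of the 5 tags with runs of A may therefore keep part of that shift after the offset.

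In all, 10563 tags were called higher and 1571 lower in the 100 µM SNP library, a share of 87.1% higher. Of the higher tags 76.1% ended in AA, against 18.7% of all tested tags, and 37.1% ended in at least 6 A against 5.53%. Of the lower tags 69.6% ended in T, against 31.0%. With the offset for the last 2 bases and the likelihood ratio test the split turned, with 553 tags higher and 2049 lower (21.3% higher), and 528 of the higher and 545 of the lower calls were shared with the main test. With the offset and the quasi-likelihood test, edgeR called 0 tags either way, with 15342 tags at an unadjusted p under 0.05, and DESeq2 without the offset called 285 higher and 20 lower.

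The comparison of 250 µM SNP with mock asked the same of the higher concentration. CATGCCTGGCTTCATCCCTTG rose from 11 copies in mock to 99 and 75 in replicates 1 and 2 (log2 fold change 3.23 ± 0.46, adjusted p = 2.8e-09). CATGGGGACAAAGGATGTACG rose from 15 to 97 and 86 copies (2.85 ± 0.43, adjusted p = 2.2e-08), and CATGTTCCCCCTCCCCTCCCC from 55 to 412 and 324 (3.00 ± 0.30, adjusted p = 4.6e-19). The folds of these 3 tags were 2.72, 2.29 and 3.15 with the offset and the likelihood ratio test. In cPTIO they had 74, 99 and 470 copies. CATGAAATAAAGATACCAAGC fell from 523 to 36 and 11 copies (-4.20 ± 0.29, adjusted p = 3.2e-43), with 214 copies in 100 µM SNP and 127 in cPTIO, and stood at -4.04 with the offset. CATGTCAGAATTATGTCGAGT fell from 300 copies to 32 in replicate 1 and was not listed in replicate 2. CATGCTGATATGTTTTTTTTG had 195 copies in mock, 129 in 100 µM SNP and 268 in cPTIO, and was listed in neither 250 µM SNP library, at least 34.2-fold lower. It differs by T21G from CATGCTGATATGTTTTTTTTT, which had 31326 copies. Among the 8 named lower tags, 4 had a neighbour at 1 base that was at least 50 times as abundant. The named higher tag CATGTCGGACTGCTTGTTGCT begins with adaptor 1 bases, had 12 copies in mock and 21 and 163 in replicates 1 and 2, and lost its call without replicate 2.

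The counts were 7623 higher and 989 lower (88.5% higher). Of the higher tags 32.2% ended in AA and 15.9% in GG, against 18.7% and 2.82% of tested tags, and 54.3% of the lower tags ended in TT against 12.5%. With the offset and the likelihood ratio test 1162 were higher and 1762 lower (39.7% higher), of which 1085 and 329 were shared with the main calls. Under the quasi-likelihood test the offset left 2 higher and 38 lower, with 15385 tags at an unadjusted p under 0.05, and DESeq2 without it called 309 and 36. By Fisher's exact test 9310 were higher and 1741 lower without replicate 1, and 14047 and 3088 without replicate 2.

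**Figure D2:**
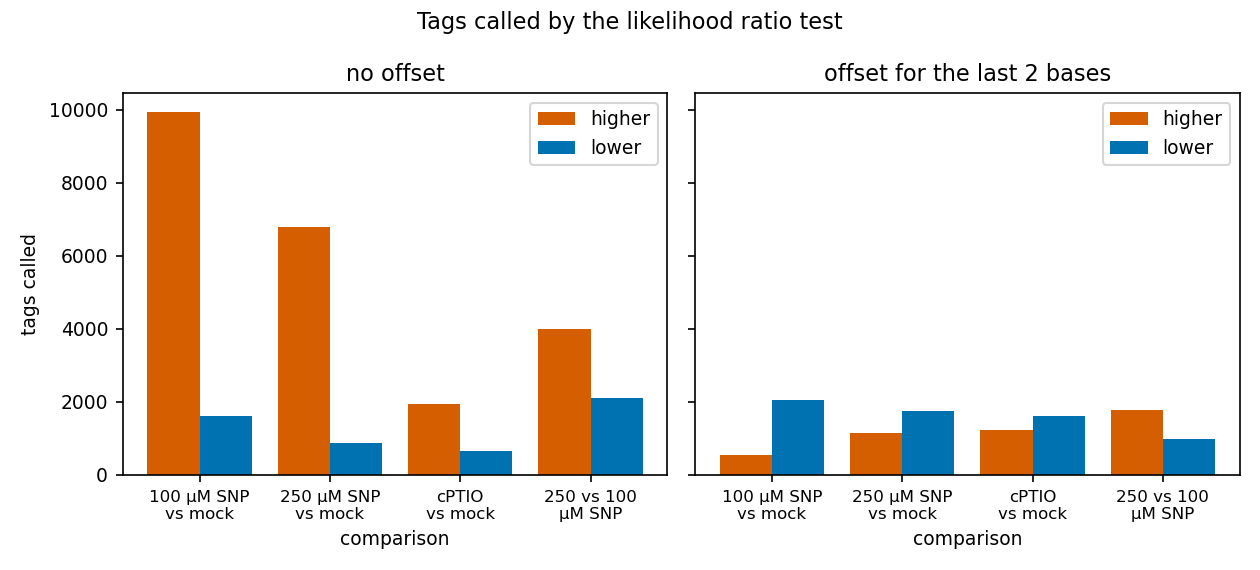
Number of tags called higher (orange) and lower (blue) by the likelihood ratio test in each comparison (x axis), without (left) and with (right) an offset for the last 2 bases of the tag. In 100 µM SNP against mock the counts are 9952 higher and 1605 lower without the offset, and 553 higher and 2049 lower with it.

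The comparison of cPTIO with mock asked what removal of nitric oxide changes. All 8 named higher tags began with CATGTCGGACTG, the CATG site followed by bases of adaptor 1, and had log2 fold changes of 3.99 to 5.05. CATGTCGGACTGCGATACACT rose from 28 copies in mock to 499 in cPTIO (4.08 ± 0.37, adjusted p = 1.3e-23), with 11 copies in 100 µM SNP and 29 and 251 in 250 µM SNP replicates 1 and 2. DESeq2 did not call it (log2 fold change 4.04, adjusted p = 0.874). Among the lower tags, CATGAGAAGAAAGAAGAAGGC fell from 1876 to 47 copies (-5.38 ± 0.32, adjusted p = 9.0e-57) and its neighbour CATGAGAAGGAAGAAGAAGGC from 456 to 7 (-6.06 ± 0.44, adjusted p = 4.9e-38). CATGTTGTTTATTCGGCAGAA fell from 815 to 37 copies (-4.52 ± 0.32, adjusted p = 2.6e-41) and had 1550 in 100 µM SNP and 1233 and 1134 in the 250 µM SNP libraries. CATGAAATTGCCAAGCAGCAA had 173 copies in mock and 5 in cPTIO (-5.14 ± 0.48, adjusted p = 7.3e-23). With the offset and the likelihood ratio test, the fold of the adaptor 1 tag was 4.16 and those of these 4 lower tags were -5.30, -5.98, -4.92 and -5.54. Of the 8 named lower tags, 7 shared at least 6 bases in a row with adaptor 2.

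In total 2639 tags were called higher and 864 lower in cPTIO (75.3% higher). Scaled by totals alone the split was 3575 and 602 (85.6% higher), and the median log2 fold change of all tested tags was 0.20 in place of 0.08. With the offset and the likelihood ratio test 1238 were higher and 1622 lower (43.3% higher), of which 1005 and 688 were shared with the main calls. The quasi-likelihood test with the offset called 3 higher and 49 lower, with 15967 tags at an unadjusted p under 0.05. Of the 2639 higher tags, 274 began with the adaptor 1 bases, and DESeq2 called 15 tags higher and 35 lower.

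**Figure D3:**
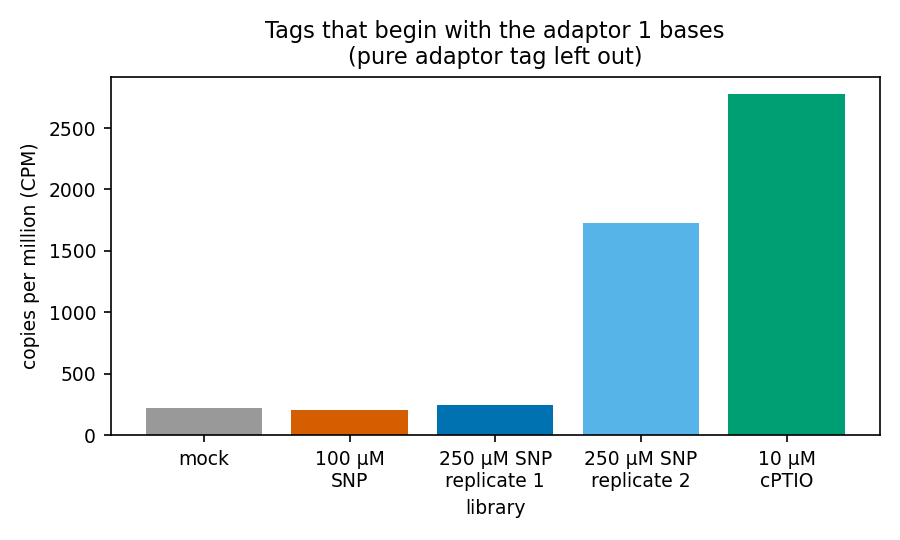
CPM of tags that begin with CATGTCGGACTG (y axis) in each library (x axis), leaving out the pure adaptor tag. The bars stand at 224.2 in mock, 208.8 in 100 µM SNP, 244.1 and 1728 in 250 µM SNP replicates 1 and 2, and 2777 in cPTIO.

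The direct comparison of 250 µM with 100 µM SNP asked how the concentrations differ. CATGTCTCTATTTATTTATTA fell from 322 copies at 100 µM to 33 in replicate 1, and was not listed in replicate 2 at 250 µM. CATGAAATAAAGATACCAAGC fell from 214 copies to 36 and 11 (-3.19 ± 0.30, adjusted p = 1.9e-22), and CATGCAAACACACATCTACAG from 130 to 13 and 29 (-2.66 ± 0.36, adjusted p = 3.6e-10). CATGCTAAAAAAAAAAAAAAA fell from 2313 to 704 and 217 copies (-2.31 ± 0.21, adjusted p = 3.4e-23). DESeq2 called neither CATGAAATAAAGATACCAAGC (-3.23, adjusted p = 0.256) nor CATGCTAAAAAAAAAAAAAAA (-2.37, adjusted p = 0.608) in this comparison. CATGTTTTGAACGGTTGTACG rose from 14 copies to 110 and 63 (2.61 ± 0.43, adjusted p = 9.7e-07), and CATGTGTACTTAAATTTTGGT from 15 to 85 and 108 (2.65 ± 0.43, adjusted p = 3.4e-07). The offset with the likelihood ratio test lowered these 2 to 2.23 ± 0.54 (adjusted p = 0.00710) and 1.82 ± 0.39 (adjusted p = 0.00144), and gave -3.07 for CATGAAATAAAGATACCAAGC and -2.47 for CATGCAAACACACATCTACAG. CATGCTAAAAAAAAAAAAAAA kept its call with it (adjusted p = 0.00103) at a smaller fold. The offset does not wholly cover tags with runs of A. In 250 µM SNP replicate 1 against 100 µM SNP, abundant tags ending in at least 6 A had a median of -0.63. Other AA tags had -0.14. Of the 8 named higher tags, 4 began with the adaptor 1 bases.

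Here 4139 tags were called higher and 2250 lower (64.8% higher), and 71.6% of the lower tags ended in at least 6 A. With the offset and the likelihood ratio test 1791 were higher and 995 lower (64.3% higher). The offset with the quasi-likelihood test left 0 higher and 1 lower, with 16806 tags at an unadjusted p under 0.05, and DESeq2 without the offset called 188 and 5 (97.4% higher). By Fisher's exact test 6578 tags were lower without 250 µM SNP replicate 1 and 1746 without replicate 2, so that the count of lower tags depended on which library of the pair was used.

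Calls overlapped between the comparisons with mock. At both SNP concentrations 2906 tags were higher and 166 lower, where independent lists would share 567.5 and 10.95, and 8 moved in opposite directions. 100 µM SNP and cPTIO shared 979 higher and 117 lower tags (196.5 and 9.57 for independent lists), with 44 in opposite directions. 250 µM SNP and cPTIO shared 1611 higher and 228 lower tags (141.8 and 6.02 for independent lists), with 22 in opposite directions. Independent lists would put more tags in opposite directions for each pair. For the SNP concentrations they would hold 73.6 tags higher at 100 µM and lower at 250 µM, and 84.4 the reverse. For 100 µM SNP and cPTIO the values were 64.3 and 29.2, and for 250 µM SNP and cPTIO 46.4 and 18.4. Unchanged groups simulated against the same mock library, with no bias of the last 2 bases, gave at most 1 shared call in the same direction for the SNP concentrations and 0 for either with cPTIO, and 0 in opposite directions. The fold changes of the SNP concentrations correlated across tags at 0.61 (simulated 0.53, covariance 0.81 against 0.29), those of 100 µM SNP and cPTIO at 0.47 (simulated 0.46, covariance 0.66 against 0.29), and those of 250 µM SNP and cPTIO at 0.73 (simulated 0.60, covariance 0.80 against 0.29). With the offsets of these bases built into each library, 10 further draws gave 19 to 61 shared calls for the SNP concentrations and at most 2 for either with cPTIO, and 0 in opposite directions. The simulated covariances then rose to 0.68, 0.58 and 0.56, and the correlations to 0.68, 0.58 and 0.70. With only 1 mock library the controls could not be split, and part of the excess over independent lists may come from it. With the offset and the likelihood ratio test, the SNP concentrations shared 145 higher and 574 lower tags (4.53 and 25.4 for independent lists), 100 µM SNP and cPTIO 127 and 290 (4.83 and 23.4), and 250 µM SNP and cPTIO 387 and 566 (10.1 and 20.1), with 0, 2 and 1 in opposite directions. The 10 biased draws gave 0 shared calls in this setting, and covariances of 0.44 for each pair against 0.61, 0.58 and 0.73 observed. Their correlations were 0.63, 0.56 and 0.69, above the observed 0.57 and 0.46 for the pairs with 100 µM SNP and below the observed 0.74 for 250 µM SNP and cPTIO. These draws held only noise, at the dispersion fitted without the offset, and the effect of the last 2 bases. After the offset, tags differing at 1 base still moved together within the technical pair (correlation 0.54). A bias of that kind in the 1 mock library was not simulated, so the draws do not separate it from a shared response.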

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

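Apart from the direct comparison of the SNP concentrations, the tests in this part were chosen after the results were seen. That comparison showed 8 tags that were called in opposite directions against mock at 100 µM and 250 µM and that also differed between the concentrations by edgeR's quasi-likelihood test. Calls in opposite directions already set the concentrations at least 2 log2 units apart, so that test adds no support. Of the 8, 2 were higher at 100 µM and lower at 250 µM, and 6 the reverse, where independent lists would give 73.6 and 84.4. CATGTTGGGAGCTCTTGGGTG had a log2 fold change of 2.54 ± 0.29 between the concentrations (adjusted p = 1.9e-14), with 235 copies in mock, 74 in 100 µM SNP, and 455 and 418 in the 250 µM SNP libraries. With the offset for the last 2 bases and the likelihood ratio test, 0 tags were called in opposite directions, because at least 1 fold against mock fell below the threshold for each of the 8: CATGTTGGGAGCTCTTGGGTG went from 1.15 ± 0.26 to 0.63 ± 0.25 in 250 µM SNP and from -1.39 ± 0.31 to -1.51 ± 0.32 in 100 µM SNP. All 8 were still called between the concentrations, this tag at 2.15 ± 0.29 (adjusted p = 2.5e-09), CATGTCTCTATTTATTTATTA at -4.13 ± 0.88 (from -4.28 ± 0.31) and CATGACGTTATTTAAAAAAAA at -2.14 ± 0.40 (from -2.47 ± 0.25). The last of these ends in a run of A, and the offset does not wholly cover the shift of such tags. With the offset and the quasi-likelihood test, 0 higher tags and 1 lower tag were called between the concentrations among all tested tags. None of the 6 tags that were higher at 250 µM was therefore called there, and at most 1 of the other 2. Each concentration had 1 plant pool.

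Fold changes followed the last 2 bases of the tag. A response of the plants as the whole cause is argued against by the technical pair, which received the same treatment and in which these bases still accounted for 38.6% of the variance (at most 0.211% in 100 permutations of the bases). Reads with a wrong A at the last base are too rare to double the tags ending in AA: the highest rate was 33.3 per 10000 copies of abundant tags ending in T (T21A, in 100 µM SNP). A library bias acting on these bases, to which the adaptor is ligated after the MmeI cut, is a candidate explanation, since they accounted for 59.7% of the variance in 100 µM SNP against mock and no position from 5 to 19 alone for more than 4.45%. The excess of tags ending in GG was shared by both 250 µM SNP libraries. Other ends shared their shifts against mock as well, such as GA (medians 0.88 and 0.71 in replicates 1 and 2), TG (0.53 and 0.53) and TT (-0.61 and -0.45). Of all ends, only TA differed in sign between the 2 libraries. The GG excess also stood without mock, with a median of 0.87 in 250 µM SNP replicate 1 against 100 µM SNP. In cPTIO against 250 µM SNP replicate 2 the GG median was -0.77. These values argue against the 1 mock library as the whole cause for GG. For the shared part of these shifts the technical pair does not separate treatment from RNA preparation. For the other ends it does not separate them from the mock library either.

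Tags that begin with adaptor 1 bases led the higher calls in cPTIO. Leaving out the pure adaptor tag, they were 7.08 times as frequent in 250 µM SNP replicate 2 as in replicate 1, which argues against a response to treatment as the whole cause, and 12.4 times as frequent in cPTIO as in mock. With that tag, which fell from 1258 CPM in mock to 108.6 in cPTIO, they made up 0.0662% and 0.327% of copies in the 250 µM SNP libraries, 0.148% in mock and 0.289% in cPTIO. Of their copies without that tag, 40.8% continued with the first 9 bases after CATG of one of the 1000 most abundant tags, against 3.84% of the copies of other tags at the same positions, but by tags the shares were 7.92% (841 of 10620) and 5.07%, so a small part of the tags carries the contrast. Adaptor 1 joined to cut tags is a candidate source of the copies that matched, and the source of the others stays open.

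In the cPTIO library 47 tags were more than 4-fold below every other library after the offset, against at most 4 in any other library, among 40952 tags. Leaving out 3 that begin with CATGTCG, 28 of 44 held at least 6 bases in a row of adaptor 2, where 10000 random draws gave 7 at most, which argues against a response to the scavenger for those tags. A 6-base run alone did not lead to loss: of 1129 searched tags with such a run, again without those that begin with CATGTCG, 28 were low, and the median log2 ratio in cPTIO was -0.04 for runs of 6 bases and -0.22 for 7, and lower for 8 (5th percentiles -0.88, -2.34 and -3.29). Most of the 28 low tags had no run longer than 6 bases. A loss of reads that resemble adaptor 2 more closely is a candidate explanation for part of the low tags. Whether the 16 low tags without a run of 6 bases follow the scavenger cannot be told apart from a property of this library, because cPTIO had 1 library.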

How the results depend on the processing

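The tag-end offset, the likelihood ratio test, both together and the removal of adaptor-like tags were chosen after seeing the data, and the other alternatives before. Results are given in the order 100 µM SNP, 250 µM SNP and cPTIO against mock, then 250 µM against 100 µM SNP, as higher and lower tags. Scaling by totals, RLE size factors, the likelihood ratio test and removal of adaptor-like tags kept all 8 counts within 1.5 times. DESeq2 called 285 and 20, 309 and 36, 15 and 35, and 188 and 5, and gave no adjusted p to 134786, 129284, 115531 and 126533 of the tested tags. Fisher's exact test called 15516 and 4487, 13096 and 2674, 9567 and 1941, and 8360 and 4438; it counts sampling noise alone. Without 1 of the 250 µM SNP libraries it called 14947 to 15152 and 4191 to 4261, 9310 to 14047 and 1741 to 3088, 9005 to 9160 and 1827 to 1848, and 5664 to 7984 and 1746 to 6578. With no filter the counts were 5298 and 749, 2735 and 807, 862 and 554, and 2116 and 1393. With at least 100 copies they were 0 and 0 (16966 tags at an unadjusted p under 0.05), 2102 and 292, 15 and 42, and 915 and 73, where the prior degrees of freedom of edgeR fell from infinite to 9.30. With no fold threshold, 1952 tags were lower in 250 µM SNP against mock. A log2 fold change of at least 2 left 3745 and 813, 2623 and 293, 1093 and 413, and 1638 and 353. An adjusted p below 0.001 left 3160 and 134, 1683 and 186, 426 and 213, and 951 and 633. The tag-end offset with edgeR's quasi-likelihood test left 0 and 0, 2 and 38, 3 and 49, and 0 and 1, with 15342, 15385, 15967 and 16806 tags at an unadjusted p under 0.05; the prior degrees of freedom fell to 8.02. The offset with the likelihood ratio test gave 553 and 2049, 1162 and 1762, 1238 and 1622, and 1791 and 995.

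The correlation of the technical pair was 0.935 with a pseudocount of 0.1 CPM and 0.968 with at least 100 copies, where 1692 tags differed in place of 2606. Overlaps in the same direction were 6029 (both SNP concentrations), 3723 (100 µM SNP and cPTIO) and 5695 (250 µM SNP and cPTIO) by Fisher's exact test, and 719, 417 and 953 with the offset and likelihood ratio test. Those in opposite directions were 40, 74 and 41, and 0, 2 and 1. The cause of these differences was not tested where none is named.

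Among 84 log2 fold changes of the named tags (64 called, and 20 of the most abundant mock tags), none changed direction while called. Total counts, RLE and Fisher's exact test kept every call. The offset with the likelihood ratio test ended 2 calls and added 1 (CATGAGGTGAATTTTTATGTG, the most abundant mock tag, lower in cPTIO). The offset with the quasi-likelihood test left 0 calls over all tags in 100 µM SNP against mock, so every named call there ended. It left 2 higher and 38 lower tags in 250 µM SNP, 3 and 49 in cPTIO, and 0 and 1 in 250 µM against 100 µM SNP. Most of the named higher calls therefore ended with it in every comparison. DESeq2 gave an adjusted p to 38 of the 84, which include abundant mock tags that had no call to lose. It ended 9 calls: CATGTCGGACTGCTTGTTGCT (4.42, adjusted p = 0.758) and CATGTCGGACTGCGATACACT (4.04, adjusted p = 0.874) in cPTIO against mock, and 7 in 250 µM against 100 µM SNP. These 7 were CATGTCGGACTGCGATACACT (3.57, adjusted p = 0.570), CATGTCGGACTGTTTTTATTT (2.84, 0.688), CATGTCGGACTGCTCAAAGCA (2.53, 0.719), CATGAAATAAAGATACCAAGC (-3.23, 0.256), CATGACGTTATTTAAAAAAAA (-2.52, 0.544), CATGACGTTATTTATGAAAAA (-2.42, 0.540) and CATGCTAAAAAAAAAAAAAAA (-2.37, 0.608). Their folds stayed above the threshold, and the calls ended on the adjusted p. The 9 ended calls are a larger share of the calls that DESeq2 could test than 9 of 38, since the 38 include uncalled tags. Without 250 µM SNP replicate 2, CATGTCGGACTGCTTGTTGCT lost its call against mock (log2 fold change 1.10) and against 100 µM SNP (1.43). Matching tags to genes, and with it the alternatives on shared tags and 3'-most sites, and the gene-list medians with their scalings and filter, were not run, since no transcript sequence was used; single tags were already the features. No paired analysis was possible because the groups share fewer than 2 replicate numbers. In simulated data without bias, 4-fold changes were recovered in 9.5% of tags with 25 to 99 summed copies against 93.5% of tags with at least 250, so a tag without a call is not shown to be unchanged.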

Other observations

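The tests in this part were chosen after the results were seen. Tags with long runs of A, whose origin was not tested, differed between libraries: the tag with A at all 17 bases after CATG, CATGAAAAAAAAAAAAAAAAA, had 7994 copies in mock, 32144 in 100 µM SNP, 11147 and 2554 in 250 µM SNP replicates 1 and 2, and 2761 in cPTIO. The median log2 ratio of abundant tags ending in at least 6 A was 1.79 in 100 µM SNP against mock and -0.97 within the technical pair. The pure adaptor 1 tag CATGTCGGACTGTAGAACTCT had 20545 copies in mock, 14111 in 100 µM SNP, 5475 and 21746 in the 250 µM SNP libraries, and 1711 in cPTIO.

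Rates of 1-base neighbours at the last position differed between libraries as well. Per 10000 copies of abundant tags ending in G, G21C neighbours had 16.9 copies in mock, 11.1 in 100 µM SNP, 4.31 and 3.96 in the 250 µM SNP libraries, and 4.07 in cPTIO. For T21G the values were 7.70, 4.91, 4.60, 4.56 and 5.84. Several named lower tags, such as CATGTTCTTTACCTTTGCTTG with 196 copies in mock and 47, 13, 18 and 55 in the others, are T21G neighbours of a tag with far more copies (90655 for CATGTTCTTTACCTTTGCTTT).

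A hypothesis was that tags differing at 1 base, which in tetraploid cotton may come from closely related gene copies, respond together. Over 1225 pairs of tags with at least 500 summed copies each, an abundance ratio of at most 4 and no long run of A, the log2 fold changes after the offset correlated within pairs at 0.82 in 100 µM SNP, 0.68 in 250 µM SNP and 0.81 in cPTIO against mock. Random partners with the same last 2 bases reached at most 0.068, 0.091 and 0.14 in 100 draws. Within the technical pair the correlation was 0.54 (at most 0.092 for random partners), so a library bias set by the tag sequence is a candidate source of at least part of it. Whether related gene copies respond together cannot be told apart from that bias here, since each treatment had 1 plant pool and the tags were not matched to genes.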
